A study of Oncorhynchus mykiss with 14 samples.

How the data were processed

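Small RNA libraries from mature adipocytes of adult rainbow trout were analysed for 3 fat depots: visceral (VAT, 4 libraries), subcutaneous (SAT, 5 libraries) and intramuscular (IMAT, 5 libraries). Per the labels' protocols, fish were kept at 15 ± 1 °C with 12 h of light and 12 h of darkness, received no treatment and were fasted for 24 h. The depots were dissected, adipocytes were released with collagenase type II and total RNA was taken up in TRIzol. A company made and sequenced the small RNA libraries. Samples were grouped by the depot in their titles. Replicate numbers come from the titles, and VAT has no library with the number 2. Nothing in the labels states that samples within a depot came from separate fish, so the p-values measure the spread between these samples, which may be technical.

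The deposited table holds whole-number read counts per miRNA for each library, not scaled by the authors, and a second column per library whose header calls it TPM. Each of these deposited values equals the count as a share of the library's summed counts on the CPM scale, within 0.005, so they are CPM values with no length term. The divisor used by the authors leaves out the first miRNA of the table, ssa-miR-19c-4-3p, which was above 0 in 5 libraries. No column holds the unit that the name of the deposited table announces. A further column gives the length of the mature sequence, 18 to 25 nt. There were 2 further columns of per-sample values whose names match no sample label, and they were not used here. Trimmomatic 0.30 and edgeR 3.4.6 are named, without a role, per the submitters' processing notes. The aligner, the miRNA caller and the genome build are not given in the sources used here, and no genome coordinates or sequences are reported.

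The table lists 899 entries: 256 carry Atlantic salmon names (prefix ssa) and 643 are predicted miRNAs without a miRBase-style name. Some entries carry the same reads. Entries were treated as linked when both were above 0 in at least 4 libraries, reached at least 20 reads in 1 of these, and differed in each of them by no more than the larger of 2 reads and 10%. This gave 52 sets with 121 entries. The 3 entries for miR-1, the pair for miR-133a and the pair for miR-203a are such sets and were counted as 1 name. In 15 sets of named miRNAs both arms of the precursor carried the same counts, so the arm is uncertain (miR-193, miR-216b and miR-7132b among those reported). Some zeros lie beyond counting error: 97 of the 327 tested entries, 38 of them named, were listed at 0 in a library where the lowest share above 0 among the depot's other libraries would give at least 20 reads at that library's depth. In 47 cases an entry was listed at 0 beside a linked entry with at least 20 reads. Such values are therefore described as listed at 0.

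The comparison written before the data were examined was limma on log2 values, chosen because the name of the table announced FPKM. Because the table holds counts, the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the deposited counts was used in its place, with TMM scaling, all 14 libraries in 1 fit and no block. Entries above 0 in at least 4 libraries were tested (327, of which 228 named). All edgeR tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05 (a difference past it is a call). Log2 fold changes are given with their standard error (SE), and the depot named first minus the second. Levels are TMM-scaled CPM, mean ± SD. Whole profiles were compared by PERMANOVA on Euclidean distances of log2(deposited CPM + 1) with 100000 shuffles of the depot labels. Shares of a library's counts were compared on the log2 scale by two-sided exact permutation tests, adjusted by Benjamini-Hochberg over the 6 share tests, and a share given for a single library has its exact Clopper-Pearson 95% interval. Intervals cover counting error only, since reads of a PCR-amplified library are not independent molecules.

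Before the data were examined, 17 lists of miRNA numbers were fixed. Markers of other cell types covered muscle, red blood cells, white blood cells, endothelium, epithelia and skin, stroma and smooth muscle, gut and liver, pancreas, and neurons and sensory cells. The other lists held miRNAs described as promoting fat cell formation, as restraining it, or as promoting brown or beige fat, miRNAs of lipid and insulin metabolism, miRNAs of the Hox clusters, miRNAs induced in inflammation, the miR-17-92 family, and let-7 with miR-98. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over all 45 list tests, and again with an estimated correlation and with the mean per miRNA number in place of single entries. The preset takes members as nearly uncorrelated, which entries with the same reads, and the muscle miRNAs within depots, were not. Its p-values can therefore be too small for such lists. As planned, fry was run beside camera. It asks whether a list changed at all, in 1 direction or in mixed directions, and not whether it changed more than the other entries. Its p-values are unadjusted and are given for lists that camera did not call. Red blood cells (2 entries) and endothelium (1 entry) had fewer than 3 tested entries and received no set test. The let-7 family is also part of the list restraining fat cell formation. The rule for naming miRNAs was fixed at the same time. It takes, per comparison, the 10 largest called differences in each direction among miRNAs with a miRBase-style name at or above the median level of the tested entries, up to 4 members of each list with the smallest p, and the 10 most abundant miRNAs.

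Other settings tried were other pseudocounts, filters, scalings (median ratio, quantile, muscle miRNAs left out of the totals), a replicate block, array quality weights, a robust fit, a fit of only the 2 depots compared, a minimum log2 fold change of 1, and leaving out each library in turn. The pseudocount, quantile and weight alternatives were run in limma, because the count test has no pseudocount, and so change the test as well. The planned limma test on log2 values was kept as an alternative once edgeR had replaced it. Alternatives chosen after seeing the data were DESeq2 1.42.0, library totals without further scaling, linked entries joined, entries with a zero beyond counting error left out, and named entries only. The test was run on simulated counts with the libraries' own means and depths, with 60 entries changed per simulated table. Over 5 tables per comparison, the share of 4-fold changes found was 29.3% for IMAT against VAT, 26.0% for SAT against VAT and 25.3% for IMAT against SAT. For 16-fold changes it was 57.3%, 62.0% and 62.7%, and the false share of the calls was 9.09%, 5.71% and 4.35%.

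Library totals ranged from 759369 to 11843805 counts, and 219 to 435 entries were above 0 per library. Reads of linked entries count more than once in these totals. No 2 libraries of a depot agreed within sampling noise, so none was taken for a library deposited more than once. This does not show that they are separate biological samples.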

Results

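Small RNAs of mature adipocytes, the lipid-filled cells of fat tissue, were counted in 14 libraries from 3 fat depots of rainbow trout: 4 libraries of visceral fat (VAT, replicates 1, 3, 4 and 5), 5 of subcutaneous fat (SAT) and 5 of intramuscular fat (IMAT). The design compares the 3 depots of untreated fish, and so asks which miRNAs differ between adipocytes of different places in the body. In VAT the libraries held 5332078, 4525742, 6666016 and 11076843 summed counts on miRNA entries (mean 6900000 ± 2920000, SD, n = 4). In SAT, replicates 1 to 5 held 2060776, 3734754, 4042846, 2757708 and 3843442 counts (3290000 ± 846000, n = 5). In IMAT they held 3621364, 4429852, 2564208, 759369 and 11843805 counts (4640000 ± 4250000, n = 5). These sums count the reads of linked entries more than once, most of all in IMAT. With linked entries joined, the VAT libraries held 5188017, 4292046, 6153251 and 10813567 counts. The SAT libraries then held 1860052, 3458496, 3655515, 2616632 and 3611345, and the IMAT libraries 1714410, 2006839, 1211015, 407941 and 6912879. Per library, 390 ± 40.2 entries were above 0 in VAT, 306 ± 21.5 in SAT and 261 ± 42.5 in IMAT. Predicted miRNAs without a miRBase-style name took 1.5 ± 0.217% of the summed counts in VAT, 1.30 ± 0.128% in SAT and 0.362 ± 0.145% in IMAT.

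The depot accounted for 50.7% of the variance between whole miRNA profiles of deposited CPM (permutation test on Euclidean distances, 14 libraries, p = 3e-05). With TMM scaling, not planned for this test, the share was 41.7%, and with the muscle miRNAs left out of the totals 40.2%. The first principal component held 34% of the variance and the second 14.3%. Correlations across miRNAs, which are not independent replicates, had a median r of 0.91 (0.83 to 0.97) over the 26 pairs of libraries of 1 depot and of 0.85 (0.69 to 0.93) over the 65 pairs of different depots.

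**Figure D1:**
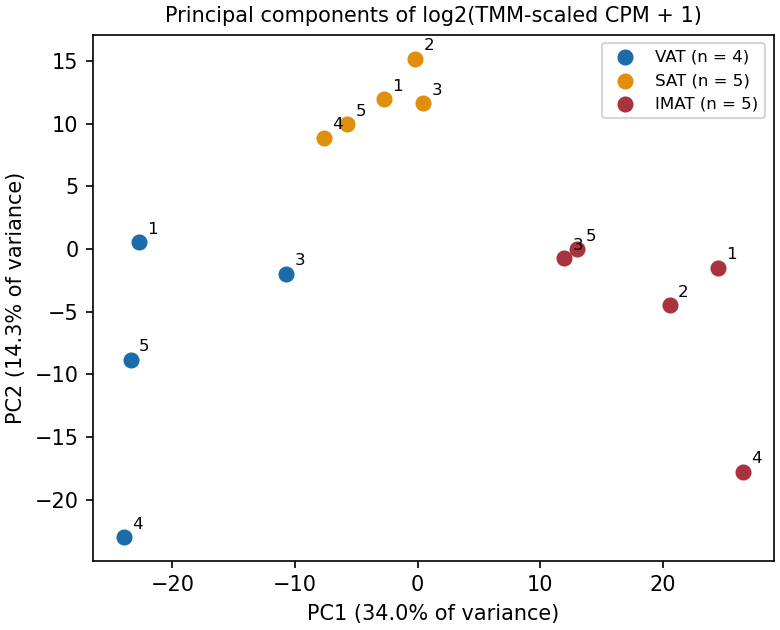
Principal components of log2(TMM-scaled CPM + 1), with PC1 (34% of the variance) on the x axis and PC2 (14.3%) on the y axis; each point is 1 library, coloured by depot (VAT n = 4, SAT n = 5, IMAT n = 5) and marked with its replicate number. The 4 VAT libraries lie at PC1 values from -23.94 to -10.7, the SAT libraries from -7.621 to 0.4787 and the IMAT libraries from 11.94 to 26.54.

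miR-1-3p, which is made in heart and skeletal muscle, was the most abundant miRNA of IMAT, with a normalised read count (TMM-scaled CPM) of 516000 ± 256000 (SD, n = 5), against 16200 ± 9720 in SAT (n = 5) and 2150 ± 3530 in VAT (n = 4). As 1 of 3 linked entries for miR-1, it took 21.1 to 27.2% of the summed IMAT counts. That sum holds the same reads once per linked entry, so the miR-1 share of the reads themselves was higher. The TMM factors of IMAT, 0.301 in IMAT 2 to 0.842 in IMAT 4, raise its scaled values above the shares and widen their spread. miR-206, made in skeletal muscle, held 113000 ± 60700 in IMAT, 6970 ± 3600 in SAT and 503 ± 760 in VAT. miR-146a, which is induced by NF-kB and restrains its signalling, had the highest mean in VAT, 222000 ± 135000, against 63500 ± 20500 in SAT and 27400 ± 10300 in IMAT. It led in VAT 1 and VAT 3, while miR-100a led in VAT 4 (21.1% of the counts against 9.83%) and miR-21b in VAT 5 (33.8% against 31.3%). The other 7 of the 10 most abundant are given next, without a rank against these. In the order VAT, SAT and IMAT, miR-100a held 59700 ± 56800, 97600 ± 24400 and 46000 ± 21900, and miR-21b 83000 ± 93200, 64900 ± 15300 and 31700 ± 6620. miR-22a held 49300 ± 25100, 67900 ± 14200 and 20300 ± 4920, and the endothelial miR-126 held 20100 ± 14700, 46600 ± 7540 and 19100 ± 7710. For let-7a the values were 27900 ± 15700, 37400 ± 10300 and 19600 ± 7000, for let-7e 36600 ± 25700, 23400 ± 5310 and 14900 ± 15600, and for miR-10b, of a Hox cluster, 6930 ± 8540, 28500 ± 3590 and 23600 ± 20900. Single libraries raised several of these means: VAT 3 for miR-1-3p (7420 CPM, the nearest VAT library 782) and miR-206 (1640, nearest 231), VAT 5 for miR-21b (222000, nearest 51900), and VAT 4 for miR-10b (19700, nearest 3100). In IMAT they were IMAT 2 for miR-206 (217000, nearest 98100), and IMAT 5 for let-7e (42600, nearest 9360) and miR-10b (60600, nearest 19200). Without VAT 5 every VAT library of miR-21b lay at or below 51900, so its higher mean in VAT than in SAT rests on 1 library.

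The list of muscle miRNAs took 80.6 ± 9.17% of all counts in IMAT (65.5 to 89.6%, n = 5), 7.56 ± 3.25% in SAT (3.37 to 11.9%, n = 5) and 1.29 ± 2.24% in VAT (0.0888 to 4.65%, n = 4). The VAT mean rests on VAT 3 (4.65%), as VAT 1, VAT 4 and VAT 5 held 0.297, 0.0888 and 0.13%. Entries with the same reads inflate these shares; with linked entries joined they were 64.3 ± 12.7%, 3.55 ± 1.56% and 0.542 ± 0.933%. The share differed between IMAT and VAT (two-sided exact permutation test, p = 0.0079, adjusted p = 0.012) and between IMAT and SAT (exact p = 0.0079, adjusted p = 0.012), where no library of one depot reached the other. SAT and VAT also differed (exact p = 0.016, adjusted p = 0.016), with SAT 4 at 3.37% below VAT 3 at 4.65%. The exact 95% Clopper-Pearson interval was 3.35 to 3.39% for SAT 4 and 4.63 to 4.67% for VAT 3. miR-146a alone took 31.9 ± 15.7% in VAT (9.83 to 43.5%), 8.55 ± 1.56% in SAT (6.61 to 10.6%) and 1.58 ± 0.884% in IMAT (0.521 to 2.86%), with the same exact and adjusted p in each of the 3 comparisons. VAT 4, at 9.83% (9.81 to 9.85%), lay below SAT 2, at 10.6% (10.6 to 10.7%).

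**Figure D2:**
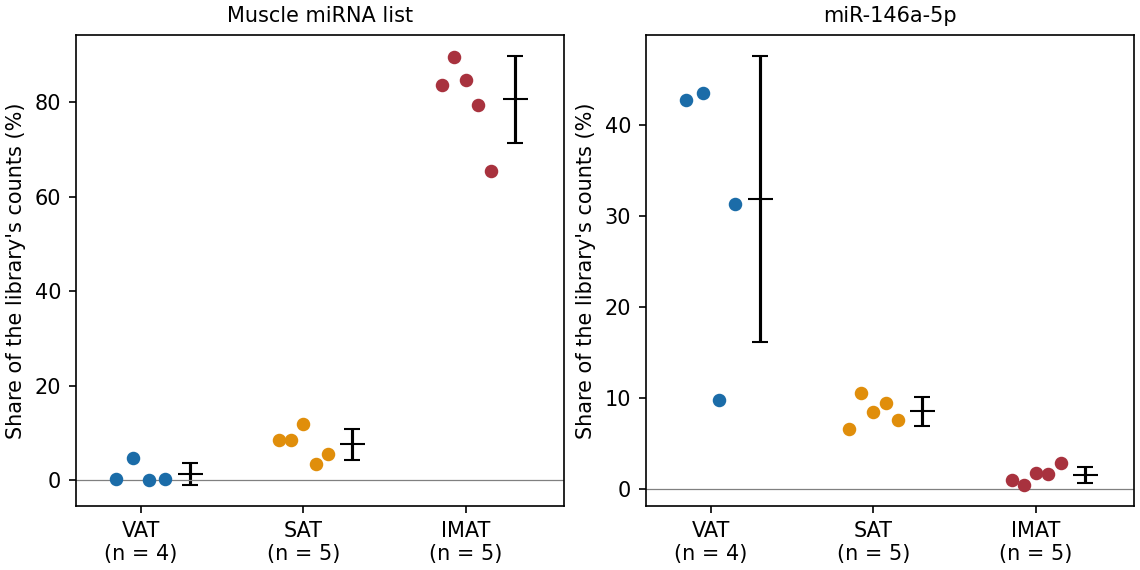
Share of each library's counts (y axis, percent) on the muscle miRNA list, at left, and on miR-146a, at right; each point is 1 library of VAT (n = 4), SAT (n = 5) or IMAT (n = 5), and the bar beside them gives mean ± SD. The muscle list took 65.5 to 89.6% in IMAT, and miR-146a took 9.83 to 43.5% in VAT.

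IMAT and VAT were compared to ask how fat between muscle fibres differs from fat around the viscera. Among named miRNAs at or above the median level, the largest called differences were in miRNAs of muscle, whose share of counts was 65.5 to 89.6% in IMAT and 0.0888 to 4.65% in VAT. miR-133a, which is transcribed with miR-1 in muscle, was higher in IMAT by a log2 fold change of 7.92 ± 1.12 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00035). miR-1 was higher by 7.91 ± 1.31 (adjusted p = 0.00086) and miR-206 by 7.81 ± 1.16 (adjusted p = 0.00051). miR-499a and miR-499b, which lie in a myosin gene, were higher by 6.0 ± 0.77 and 4.96 ± 0.76 (adjusted p = 0.00018 and 0.00064). miR-26d was higher by 5.95 ± 0.70 (adjusted p = 0.00013). The Hox-cluster miRNAs miR-196a and miR-196b, of the posterior body, were higher by 5.90 ± 1.18 and 5.28 ± 0.55 (adjusted p = 0.0037 and 6.2e-05). miR-204, which favours fat over bone formation in stromal cells, was higher by 4.36 ± 0.56 (adjusted p = 0.00018). For each of these 9 names, every IMAT library (n = 5) lay above every VAT library (n = 4), and each kept its call in every alternative that tested it. miR-196a was listed at 0 in 2 VAT libraries.

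In IMAT the skin miRNAs miR-203a, miR-203b and miR-205b were higher than in VAT by 2.40 ± 0.45, 3.32 ± 0.89 and 3.16 ± 0.82 (edgeR adjusted p = 0.0024, 0.022 and 0.02). miR-27b, which restrains adipocyte formation, was higher by 1.65 ± 0.36 (adjusted p = 0.0063), and these 4 did not overlap between the depots. miR-210-5p, of the hypoxia-induced miR-210 precursor, was higher by 2.29 ± 0.50 (adjusted p = 0.0063) with overlapping libraries. With library totals as the only scaling, none of these 5 passed (miR-203a 1.08, miR-203b 2.16, miR-205b 1.84, miR-27b 0.14, miR-210-5p 0.74, edgeR adjusted p = 0.12, 0.079, 0.12, 0.72 and 0.14). Over all alternatives the highest adjusted p was 0.61, 0.8, 0.37, 0.9 and 0.21 in the same order. miR-203b lost its call without VAT 1 (adjusted p = 0.059), VAT 3 (0.05) or VAT 5 (0.071), and miR-205b without VAT 1 (0.084), VAT 5 (0.066) or IMAT 4 (0.056). Both also lost it without a filter (3.47 and 3.11, edgeR adjusted p = 0.087 and 0.15) and in the fit of only IMAT and VAT (3.41 and 3.28, 0.067 each). In limma on log2 values none of the 5 passed either, and of 31 alternatives the calls were kept in 26, 20, 21, 26 and 26.

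The inflammation-induced miR-146a was lower in IMAT than in VAT, with a log2 fold change of -3.02 ± 0.49 (edgeR adjusted p = 0.00086). The 3p arms of the neuronal miR-9a and miR-9b were lower by -2.73 ± 0.51 and -2.77 ± 0.60 (adjusted p = 0.0024 and 0.0063). miR-365, which promotes brown fat in mice, was lower by -2.54 ± 0.53 (adjusted p = 0.0048) and miR-458 by -1.70 ± 0.36 (adjusted p = 0.0048). The liver miRNA miR-122 was lower by -2.67 ± 0.61 (adjusted p = 0.0087), and miR-192a and miR-194a of gut and liver by -1.70 ± 0.39 and -2.41 ± 0.68 (adjusted p = 0.0087 and 0.029). Of these 8, only miR-194a overlapped between the depots. With the muscle miRNAs left out of the totals, miR-458 (-0.64, edgeR adjusted p = 0.21), miR-122 (-1.53, 0.15), miR-192a (-0.59, 0.38) and miR-194a (-1.26, 0.23) did not pass. These were the highest adjusted p of the 4 over all alternatives. Quantile normalization in limma also ended the call of miR-194a (-1.47, adjusted p = 0.14), and the missing filter those of miR-194a (-2.26, edgeR adjusted p = 0.21), miR-192a (-1.50, 0.17), miR-122 (-2.41, 0.053) and miR-9b (-2.41, 0.059; highest over all alternatives 0.076). In the fit of only IMAT and VAT, miR-458 (-1.49, edgeR adjusted p = 0.056), miR-122 (-2.39, 0.052), miR-192a (-1.43, 0.11) and miR-194a (-2.16, 0.14) did not pass. Of 31 alternatives these 4 kept their calls in 29, 26, 24 and 21. miR-122 lost its call without IMAT 1 (adjusted p = 0.062) or IMAT 2 (0.053), miR-192a without VAT 1 (0.076), IMAT 1 (0.063) or IMAT 2 (0.067), and miR-194a without VAT 1 (0.11), IMAT 1 (0.068), IMAT 2 (0.11) or IMAT 4 (0.096).

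miR-146d, a second form of miR-146, was lower in IMAT than in VAT by -2.52 ± 0.66 (edgeR adjusted p = 0.021), and miR-27c, a relative of miR-27b, by -1.22 ± 0.33 (adjusted p = 0.022). miR-29b-2-3p, of an insulin-sensitivity family, was lower by -1.56 ± 0.42 (adjusted p = 0.022), miR-8159 by -2.45 ± 0.69 (adjusted p = 0.029) and miR-7132b by -2.22 ± 0.67 (adjusted p = 0.04). Only miR-29b-2-3p did not overlap between the depots. Each of the 5 lost its call without IMAT 1, IMAT 2 or IMAT 4 (adjusted p = 0.057 to 0.14). miR-8159, miR-7132b and miR-29b-2-3p also lost it without VAT 1 (0.11, 0.053 and 0.053), miR-146d, miR-7132b and miR-29b-2-3p without VAT 5 (0.083, 0.21 and 0.06), and miR-7132b and miR-29b-2-3p without IMAT 3 (0.085 and 0.062). miR-7132b further lost it without SAT 1, 2, 3, 4 or 5 (0.052 to 0.054). With the muscle miRNAs left out of the totals none of the 5 passed (-1.49, -0.27, -0.61, -1.26 and -1.30, in the order of naming, edgeR adjusted p = 0.12, 0.66, 0.39, 0.27 and 0.19), and over all alternatives the highest adjusted p was the same except for miR-7132b (0.21). Quantile normalization in limma also ended the calls of miR-146d (-2.28, adjusted p = 0.062), miR-7132b (-1.49, 0.15) and miR-29b-2-3p (-0.90, 0.18). Nor did any of the 5 pass without a filter (-2.48, -1.01, -1.54, -2.30 and -2.16, in the order of naming, edgeR adjusted p = 0.059, 0.2, 0.25, 0.11 and 0.15) or in the fit of only IMAT and VAT (-2.21, -1.06, -1.36, -2.16 and -1.93, adjusted p = 0.1, 0.17, 0.16, 0.17 and 0.17). Of 31 alternatives the calls were kept in 22, 24, 20, 22 and 13.

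Of 9 muscle entries (6 distinct miRNAs), 8 were higher in IMAT than in VAT (5 distinct) and none lower (9 higher adjusted over the list alone), with a median log2 of 7.91 (camera adjusted p = 1.3e-16; adjusted p = 0.112 with an estimated correlation). Of 5 Hox-cluster entries 2 were higher (3 adjusted over the list alone), with a median of 1.77 (camera adjusted p = 0.00153; adjusted p = 0.189 with an estimated correlation). All 3 gut and liver entries were lower (3 adjusted over the list alone), with a median of -2.41 (camera adjusted p = 0.0356; adjusted p = 0.288 with an estimated correlation). Of 3 neuronal entries 2 were lower (3 adjusted over the list alone), with a median of -2.77 (camera adjusted p = 0.0356; adjusted p = 0.189 with an estimated correlation). The gut and liver call was kept in 10 of 29 alternatives, the neuronal call in 18 of 27 and the Hox-cluster call in 26 of 28. The gut and liver call was lost in limma on log2 values, with quantile normalization, median-ratio scaling, the stricter filter, the muscle miRNAs left out of the totals, linked entries joined, the mean per miRNA number, and entries with a zero beyond counting error left out. The last also ended the Hox-cluster call, and limma on log2 values, library totals and joined entries ended the neuronal call. The gut and liver call was also lost without VAT 1, VAT 3, VAT 4, SAT 4, IMAT 1, IMAT 2 or IMAT 5 (camera adjusted p = 0.056 to 0.1), and the neuronal call without VAT 3 (0.056) or VAT 4 (0.086). The other 11 lists with a set test were not called by camera (adjusted p = 0.371 to 0.908). For these, the unadjusted fry p was 6.62e-05 for the miR-17-92 family, 0.00123 for pancreas and 0.0417 for white blood cells. For the others it was 0.226 to 0.939. The fry p for mixed directions was 2.37e-08 for promoting fat cell formation, 1.03e-07 for epithelia and 0.000104 for inflammation, and 0.00117 to 0.908 for the others.

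Among those 11 lists, the epithelial list had 4 higher entries of 12 (3 distinct of 8; 4 higher and 3 lower adjusted over the list alone) and the list promoting fat cell formation had 2 higher of 14. The list restraining it had 1 higher and 1 lower of 28, the brown fat list 1 lower of 7, and the lipid and insulin list 1 lower of 12. The inflammation list had 2 lower of 10 (3 higher and 4 lower adjusted over the list alone). No entry passed among white blood cells (3), stroma (7), pancreas (6), the miR-17-92 family (18) or let-7 (10), nor in red blood cells (2) or endothelium (1), which had no set test. Medians of epithelia (-0.98) and of fat cell formation (-0.53) were negative with a positive mean (0.17 and 0.01) and an upward test. The restraining list (-0.19), brown fat (-0.04) and let-7 (-0.19) had a negative median and mean with an upward test. With the muscle miRNAs left out of the totals, the medians of the lists for red blood cells, endothelium, epithelia, stroma, promoting and restraining fat cell formation, brown fat, lipid and insulin, and let-7 turned from negative to positive (0.08 to 1.01). The lipid and insulin median was also positive with quantile normalization (0.28). Called entries turned too: with library totals 8 epithelial, 16 restraining, 7 let-7 and 6 inflammation entries were lower and none higher, and with the muscle miRNAs left out 4, 6, 3 and 4 were higher. The list promoting fat cell formation had 1 higher and 8 lower with library totals, and 2 higher and none lower with the muscle miRNAs left out. Stroma had 6 lower with library totals and no call with the muscle miRNAs left out.

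Between IMAT and VAT, 44 of 327 entries differed, 25 higher and 19 lower in IMAT (edgeR, adjusted p under the threshold; 111 at an unadjusted p under 0.05). Of all 327 entries 49 (15%) did not overlap between the depots, where chance gives 1.59%, and 33 of the 44 were among them. The median log2 of all entries was -0.60 with TMM and -0.66 with median-ratio scaling (25 higher, 28 lower). It was -2.00 with library totals (18 of 162 higher) and 0.30 with muscle miRNAs left out of the totals (57 higher, 6 lower), so the split between higher and lower followed the scaling. Quantile normalization in limma gave 50 higher and 27 lower. The count was 68 without VAT 4 and 68 without IMAT 5.

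SAT and VAT were compared to ask how fat under the skin differs from fat around the viscera. miR-204, which favours fat formation, was higher in SAT by a log2 fold change of 5.78 ± 0.60 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.1e-05). The posterior Hox-cluster miRNAs miR-196a and miR-196b were higher by 5.67 ± 1.17 and 4.15 ± 0.52 (adjusted p = 0.0056 and 0.00018). miR-99, which acts on mTOR signalling, was higher by 3.67 ± 0.36 (adjusted p = 2.5e-05), and let-7c, which restrains adipocyte formation, by 2.20 ± 0.47 (adjusted p = 0.0067). The skin miRNAs miR-205b, miR-203b and miR-203a were higher by 4.52 ± 0.87, 3.70 ± 0.91 and 2.71 ± 0.46 (adjusted p = 0.0033, 0.018 and 0.0016). miR-27b was higher by 2.03 ± 0.37 (adjusted p = 0.0025) and miR-725 by 2.65 ± 0.61 (adjusted p = 0.012). For each of these 10, every SAT library (n = 5) lay above every VAT library (n = 4). miR-203b lost its call without VAT 1 (adjusted p = 0.066) or VAT 5 (0.058), and miR-725 without VAT 1 (0.08). let-7b was higher by 1.41 ± 0.41 (adjusted p = 0.039) with overlapping libraries, and lost its call without VAT 1, VAT 3, VAT 5, IMAT 4 or any 1 of the 5 SAT libraries (0.057 to 0.1). let-7b also lost it with median-ratio scaling (1.04, edgeR adjusted p = 0.072), library totals (1.30, 0.098) and the muscle miRNAs left out of the totals (1.40, 0.057), with a highest adjusted p over all alternatives of 0.15. Without a filter miR-205b, miR-203b, miR-203a, miR-27b and miR-725 did not pass (edgeR adjusted p = 0.075, 0.11, 0.06, 0.054 and 0.15, their highest over all alternatives), nor did let-7b (0.14), which also failed in the fit of only SAT and VAT (1.11, edgeR adjusted p = 0.14) and was kept in 15 of 31 alternatives. The others not kept throughout were miR-205b, miR-203a and miR-27b (30 of 31 each), miR-725 (29) and miR-203b (28).

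Muscle miRNAs were also higher in SAT than in VAT, where their share of counts was 7.56% (3.37 to 11.9%) against 1.29% (4.65% in VAT 3, and 0.0888 to 0.297% in the other 3 libraries). miR-206 was higher by 3.79 ± 0.96 (edgeR adjusted p = 0.021), miR-499a by 3.47 ± 0.68 (adjusted p = 0.0036), miR-133a by 3.34 ± 0.90 (adjusted p = 0.028) and miR-499b by 2.48 ± 0.67 (adjusted p = 0.03). For these 4 every SAT library lay above every VAT library, while miR-1-3p did not pass (2.92 ± 1.03, adjusted p = 0.082). miR-499a kept its call in every alternative run. miR-206, miR-133a and miR-499b lost theirs with median-ratio scaling (3.08, 2.66 and 1.94, edgeR adjusted p = 0.057, 0.072 and 0.072) and with the muscle miRNAs left out of the totals (3.44, 3.04 and 2.34, adjusted p = 0.052, 0.066 and 0.052), miR-133a also with library totals (2.97, adjusted p = 0.054), and over all alternatives their highest adjusted p was 0.14, 0.19 and 0.17. Neither did they pass without a filter (3.06, 2.65 and 1.98, edgeR adjusted p = 0.11, 0.15 and 0.17) or with the stricter filter (3.15, 2.73 and 2.04, 0.054, 0.071 and 0.066), nor miR-206 and miR-133a in the fit of only SAT and VAT (3.15 and 2.74, 0.12 each). Of 31 alternatives the 3 calls were kept in 18, 16 and 18. Each of these 3 also lost its call without VAT 1, VAT 4, VAT 5, IMAT 1, IMAT 2, IMAT 3 or IMAT 4 (adjusted p = 0.059 to 0.19). miR-133a and miR-206 lost it without IMAT 5 (0.077 and 0.068), miR-133a and miR-499b without SAT 3 (0.063 and 0.067), and miR-499b without SAT 2 (0.066).

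The liver miRNA miR-122 was lower in SAT than in VAT by -4.22 ± 0.65 (edgeR adjusted p = 0.0013), and miR-192a of gut and liver by -1.28 ± 0.39 (adjusted p = 0.044). miR-216a and miR-216b, of the exocrine pancreas, were lower by -4.16 ± 0.91 and -3.96 ± 1.09 (adjusted p = 0.0077 and 0.032). miR-8159 was lower by -4.64 ± 0.75 (adjusted p = 0.0016), and the 3p and 5p arms of miR-2188 by -2.19 ± 0.53 and -1.81 ± 0.52 (adjusted p = 0.016 and 0.038). miR-146a was lower by -1.81 ± 0.47 (adjusted p = 0.027). Libraries of miR-216a, miR-216b, miR-2188-3p and miR-146a overlapped between the depots, and those of the other 4 did not. miR-146a lost its call without SAT 1 (adjusted p = 0.065), SAT 4 (0.058) or SAT 5 (0.062), and with quantile normalization in limma (-0.90, adjusted p = 0.24, its highest over all alternatives). Without any 1 of the 5 SAT libraries miR-192a and miR-216b lost theirs (0.062 to 0.1 and 0.058 to 0.075). Without VAT 1 both lost it too (0.068 and 0.052), as did miR-216b without VAT 3 (0.068). miR-2188-5p lost its call without VAT 3 (0.2), SAT 2 (0.085), SAT 3 (0.08), SAT 4 (0.074) or SAT 5 (0.088). miR-2188-5p and miR-192a also lost theirs with library totals (-2.04 and -1.27, edgeR adjusted p = 0.069 and 0.092) and with the muscle miRNAs left out of the totals (-1.98 and -1.18, adjusted p = 0.079 and 0.081). In limma miR-2188-3p (-1.92, adjusted p = 0.063), miR-2188-5p (-1.59, 0.1) and miR-192a (-1.26, 0.063) did not pass, nor did miR-2188-3p with array quality weights (-1.51, 0.077). With quantile normalization miR-216a (-3.22, limma adjusted p = 0.052), miR-216b (-1.99, 0.19), miR-2188-5p (-1.52, 0.089) and miR-192a (-1.06, 0.06) did not, and without a filter miR-216b (-4.39, edgeR adjusted p = 0.11), miR-2188-5p (-2.35, 0.1) and miR-192a (-1.53, 0.17). Over all alternatives the highest adjusted p was 0.2 for miR-2188-5p and miR-216b, 0.17 for miR-192a, 0.12 for miR-2188-3p and 0.068 for miR-216a. Of 31 alternatives their calls were kept in 18, 20, 18, 27 and 29, and that of miR-146a in 26.

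Of 9 muscle entries (6 distinct miRNAs), 5 were higher in SAT than in VAT (4 distinct; 8 adjusted over the list alone), with a median log2 of 3.34 (camera adjusted p = 8.21e-06; adjusted p = 0.288 with an estimated correlation). Of 5 Hox-cluster entries 2 were higher (3 adjusted over the list alone), with a median of 2.04 (camera adjusted p = 0.00418; adjusted p = 0.189 with an estimated correlation). Of 12 epithelial entries (8 distinct miRNAs) 4 were higher (3 distinct; 4 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0356; adjusted p = 0.659 with an estimated correlation), and the median was -0.04 with median-ratio scaling. Of 3 gut and liver entries 2 were lower (2 adjusted over the list alone), with a median of -1.35 (camera adjusted p = 0.00749; adjusted p = 0.189 with an estimated correlation). Of 6 pancreas entries (3 distinct miRNAs) 3 were lower (miR-216a and both arms of miR-216b, which carry the same counts; 3 adjusted over the list alone), with a median of -2.29 (camera adjusted p = 0.0356; adjusted p = 0.189 with an estimated correlation). The epithelial call was kept in 9 of 29 alternatives and the pancreas call in 12 of 28. Both were lost in limma on log2 values, with the stricter filter, median-ratio scaling, linked entries joined, and entries with a zero beyond counting error left out. The epithelial call was also lost with library totals, named entries only and the mean per miRNA number, and the pancreas call with quantile normalization. Leaving out entries with such a zero ended the Hox-cluster call too (26 of 28 kept). The epithelial call was further lost without VAT 1, VAT 3, VAT 4, SAT 4, SAT 5, IMAT 1, IMAT 2, IMAT 3 or IMAT 4 (camera adjusted p = 0.053 to 0.13), and the pancreas call without VAT 3, SAT 1, SAT 2, SAT 4, IMAT 1 or IMAT 2 (0.051 to 0.082).

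The other 10 lists with a set test were not called by camera between SAT and VAT (adjusted p = 0.109 to 0.908). For these, the unadjusted fry p was 0.00331 for the miR-17-92 family, 0.0044 for neurons and 0.0578 to 0.819 for the others. The fry p for mixed directions was 2.39e-07 for promoting fat cell formation, 7.57e-05 for restraining it and 0.00573 to 0.943 for the others. The list promoting fat cell formation had 1 higher entry of 14, the restraining list 3 of 28 (3 adjusted over the list alone), let-7 2 of 10 (2 adjusted over the list alone), and the inflammation list 1 lower of 10 (1 adjusted over the list alone). No entry passed among white blood cells (3), stroma (7; 2 higher adjusted over the list alone), neurons (3), brown fat (7), lipid and insulin (12) or the miR-17-92 family (18). None passed in red blood cells (2) or endothelium (1; 1 higher adjusted over the list alone), which had no set test. Stroma (-0.12) and fat cell formation (-0.19) had a negative median with a positive mean (0.25 and 0.16) and an upward test, and inflammation (-0.21) had a positive mean (0.06) with a downward test. The restraining list and let-7, whose shared median was 0.19, turned negative with median-ratio scaling (-0.23). With quantile normalization in limma let-7 was negative (-0.02), and stroma (0.34), lipid and insulin (0.27), inflammation (0.04) and both red blood cell entries (0.10) turned positive. Neurons passed there alone among the 5 scalings (-1.30, camera adjusted p = 0.024).

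Between SAT and VAT, 41 of 327 entries differed, 24 higher and 17 lower in SAT (edgeR; 81 at an unadjusted p under 0.05), and 53 of all 327 (16.2%) did not overlap between the depots, where chance gives 1.59%, with 31 of the 41 among them. The median log2 of all entries was -0.05 with TMM, -0.10 with library totals (19 higher, 14 lower), -0.44 with median-ratio scaling (14 higher, 25 lower) and -0.01 with muscle miRNAs left out of the totals (15 higher, 13 lower). Quantile normalization in limma gave 26 higher and 12 lower. The count was 27 without VAT 1, 27 without VAT 5, 26 without SAT 2 and 26 without SAT 3.

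**Figure D3:**
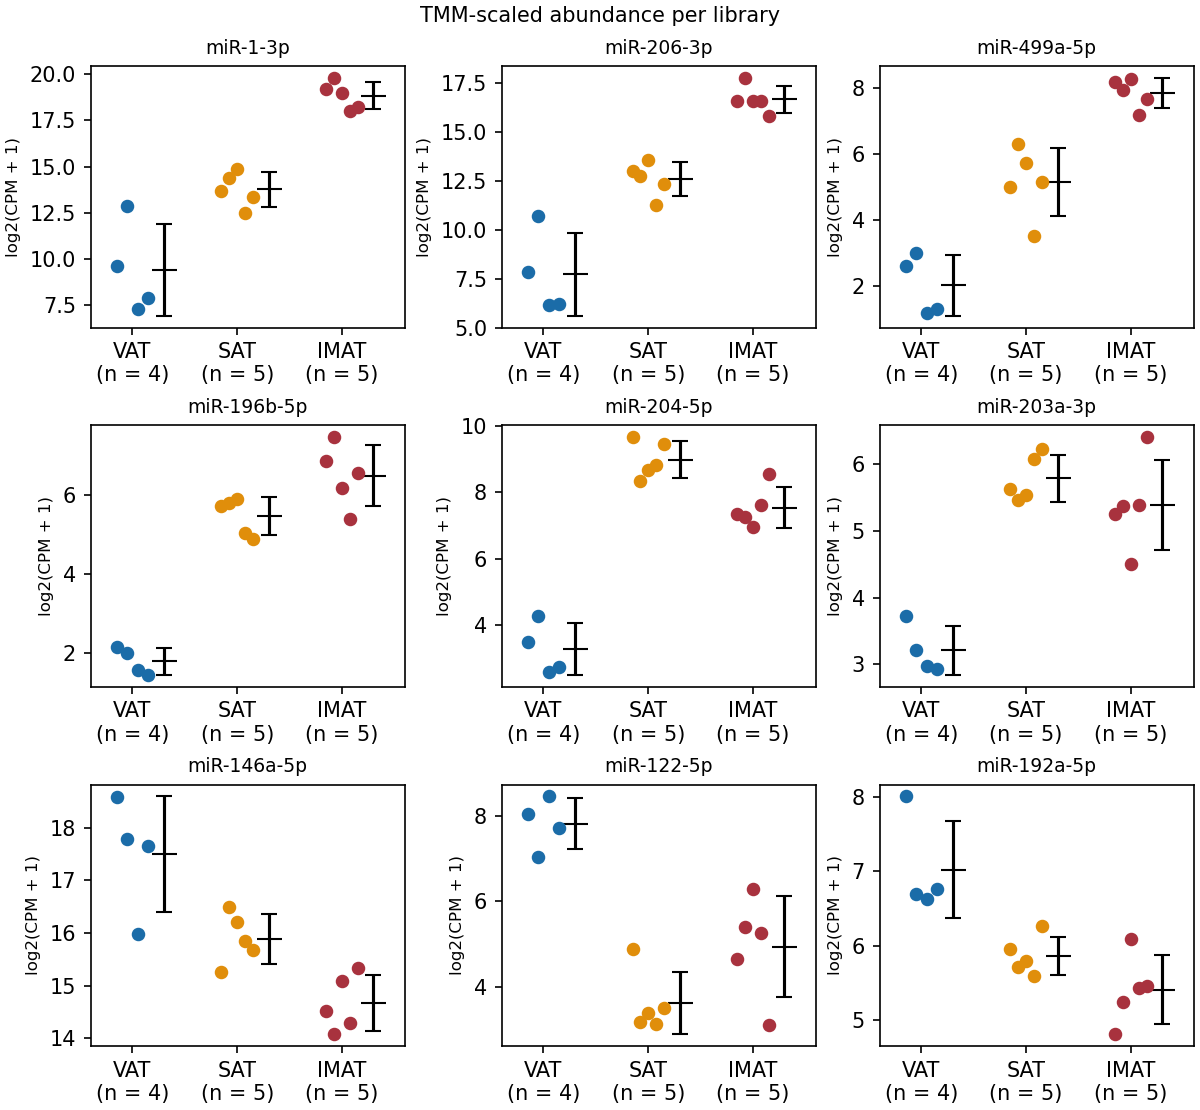
Normalised abundance, log2(TMM-scaled CPM + 1) on the y axis, of miR-1-3p, miR-206, miR-499a, miR-196b, miR-204, miR-203a, miR-146a, miR-122 and miR-192a; each point is 1 library of VAT (n = 4), SAT (n = 5) or IMAT (n = 5), with mean ± SD beside the points. The lowest SAT or IMAT library lay above the highest VAT library by a factor of 8.26 for miR-196b and 6.67 for miR-204, and none of these 9 miRNAs reversed a called difference under any scaling.

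IMAT and SAT were compared to ask how fat between muscle fibres differs from fat under the skin. The muscle miRNAs miR-1-3p, miR-133a and miR-206 were higher in IMAT by log2 fold changes of 4.99 ± 1.03, 4.58 ± 0.87 and 4.02 ± 0.88 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0089, 0.0089 and 0.011), where the muscle share of counts was 80.6% (65.5 to 89.6%) against 7.56% (3.37 to 11.9%). miR-26d was higher by 4.19 ± 0.58 (adjusted p = 0.0018), and the myosin-gene miRNAs miR-499a and miR-499b by 2.53 ± 0.59 and 2.48 ± 0.62 (adjusted p = 0.018 and 0.026). Every IMAT library (n = 5) lay above every SAT library (n = 5) for these names except miR-499b. With library totals miR-499a and miR-499b did not pass (1.21 and 0.96, edgeR adjusted p = 0.1 and 0.15; the highest over all alternatives was 0.1 and 0.24). Their calls were kept in 28 and 24 of 31 alternatives. miR-499a lost its call without SAT 5 (adjusted p = 0.054), and miR-499b without SAT 1 (0.06), SAT 4 (0.073) or SAT 5 (0.074).

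miR-365, which promotes brown fat in mice, was lower in IMAT than in SAT by -2.47 ± 0.51 (edgeR adjusted p = 0.0089) and kept its call in every alternative run. miR-125b, which is often transcribed with miR-99 and let-7, was lower by -1.96 ± 0.38 (adjusted p = 0.0089), miR-99 by -1.79 ± 0.30 (adjusted p = 0.0062) and miR-125a by -1.73 ± 0.41 (adjusted p = 0.018). miR-22a, of lipid metabolism, was lower by -1.74 ± 0.37 (adjusted p = 0.0095), the skin miRNA miR-205a-3p by -1.77 ± 0.46 (adjusted p = 0.032) and miR-29b-2-3p by -1.43 ± 0.40 (adjusted p = 0.048). For each of these 7 every IMAT library lay below every SAT library. With the muscle miRNAs left out of the totals, miR-125b (-0.97), miR-99 (-0.78), miR-125a (-0.68), miR-22a (-0.78), miR-205a-3p (-0.85) and miR-29b-2-3p (-0.46) did not pass (edgeR adjusted p = 0.15, 0.07, 0.32, 0.12, 0.25 and 0.54). Over all alternatives the highest adjusted p was the same except for miR-205a-3p (0.34). Median-ratio scaling also ended the calls of miR-125a (-1.31, adjusted p = 0.051), miR-205a-3p (-1.42, 0.057) and miR-29b-2-3p (-1.06, 0.14), the last also with quantile normalization in limma (-0.88, 0.21). Without a filter miR-125b, miR-125a, miR-22a, miR-205a-3p and miR-29b-2-3p did not pass (-1.55, -1.31, -1.33, -1.32 and -1.01, edgeR adjusted p = 0.069, 0.15, 0.11, 0.34 and 0.43). Of 31 alternatives miR-99 kept its call in 30 and these 5 in 29, 23, 27, 14 and 11. miR-22a lost its call without IMAT 2 (adjusted p = 0.058) or IMAT 4 (0.073), and miR-125a without SAT 2 (0.054), SAT 3 (0.056), IMAT 2 (0.094), IMAT 3 (0.085) or IMAT 4 (0.082). miR-205a-3p and miR-29b-2-3p lost theirs without VAT 1 (0.12 and 0.22), without any 1 of the 5 SAT libraries (0.054 to 0.13) and without IMAT 1, IMAT 2, IMAT 3 or IMAT 4 (0.12 to 0.29). miR-29b-2-3p also lost it without VAT 3 (0.057) or IMAT 5 (0.18).

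With TMM scaling the posterior Hox-cluster miRNAs miR-196a and miR-196b did not differ detectably between IMAT and SAT (0.23 ± 0.87 and 1.13 ± 0.42, edgeR adjusted p = 0.88 and 0.12), nor did miR-204 (-1.42 ± 0.45, adjusted p = 0.081). Of the Hox-cluster list, 1 entry was called higher in IMAT with median-ratio scaling (list median 0.59) and 1 with the muscle miRNAs left out of the totals (1.16). miR-146a did not pass with TMM scaling (-1.21 ± 0.45, adjusted p = 0.12), although its share of all counts, which muscle miRNAs lower in IMAT, differed as given above (exact permutation p = 0.0079, adjusted p = 0.012). Of 9 muscle entries (6 distinct miRNAs) 8 were higher in IMAT (5 distinct; 9 adjusted over the list alone), with a median of 4.58 (camera adjusted p = 5.3e-16; adjusted p = 0.112 with an estimated correlation). Of 12 epithelial entries (8 distinct miRNAs) 1 was lower (6 adjusted over the list alone), with a median of -1.32 (camera adjusted p = 0.0323; adjusted p = 0.595 with an estimated correlation). The epithelial call was kept in 10 of 29 alternatives. It was lost in limma on log2 values, with every other scaling, the stricter filter, linked entries joined and the mean per miRNA number, and without VAT 1, VAT 3, VAT 4, SAT 4, SAT 5, IMAT 1, IMAT 2 or IMAT 3 (camera adjusted p = 0.051 to 0.29). The other 13 lists with a set test were not called by camera (adjusted p = 0.278 to 0.908). For these, the unadjusted fry p was 0.00169 for neurons, 0.0149 for the miR-17-92 family, 0.0154 for restraining fat cell formation and 0.0461 for let-7. For the others it was 0.0555 to 0.769. The fry p for mixed directions was 0.0103 for inflammation, 0.0226 for restraining fat cell formation, 0.0353 for lipid and insulin and 0.0442 for brown fat, and higher for the others. Brown fat had 1 lower entry of 7 (1 adjusted over the list alone), and lipid and insulin 1 lower of 12 (1 adjusted over the list alone).

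No entry passed between IMAT and SAT among white blood cells (3), stroma (7; 2 lower adjusted over the list alone), gut and liver (3), pancreas (6), neurons (3; 2 lower adjusted over the list alone), fat cell formation (14), its restraint (28), the Hox clusters (5), inflammation (10), the miR-17-92 family (18) or let-7 (10). None passed in red blood cells (2) or endothelium (1; 1 lower adjusted over the list alone), which had no set test. White blood cells (median -0.14) and fat cell formation (-0.36) had a negative median and mean with an upward test, and gut and liver (-0.42) and the miR-17-92 family (-0.29) a negative median with a positive mean (0.02 and 0.21) and an upward test. Medians of all lists except muscle, endothelium, epithelia, stroma and neurons changed sign between the 5 scalings. Pancreas and the Hox clusters were positive except with library totals (-0.59 and -0.995), and the others were positive with the muscle miRNAs left out of the totals (0.23 to 0.93). With library totals 7 entries of fat cell formation, 4 of stroma and 2 of gut and liver were lower, and with the muscle miRNAs left out 2, 1 and 1 were higher. Library totals also gave 20 restraining, 11 epithelial, 9 let-7, 5 lipid and insulin, 4 inflammation and 2 miR-17-92 entries lower. None of these 6 lists had a call with the muscle miRNAs left out.

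Between IMAT and SAT, 22 of 327 entries differed, 12 higher and 10 lower in IMAT (edgeR; 84 at an unadjusted p under 0.05), and 61 of all 327 (18.7%) did not overlap between the depots, where chance gives 0.79%, with 18 of the 22 among them. The median log2 of all entries was -0.43 with TMM, -1.80 with library totals (7 of 131 higher), -0.06 with median-ratio scaling (16 higher, 7 lower) and 0.52 with muscle miRNAs left out of the totals (29 higher, 4 lower). Quantile normalization in limma gave 21 higher and 27 lower. The count was 47 without VAT 4 and 37 without IMAT 5. Over the 3 depots together 58 entries differed, 48 of them named.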

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

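The test of muscle material by correlation was fixed before its result was seen, while the test of a fixed makeup was chosen after the result was seen.

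In 8 of 45 groups of libraries, the highest library lay far from the others by Dixon's test at the 95% level. Chance gives about 1 in 20 for normal values in independent groups. The values were not put on a log scale, and the muscle flags of VAT 3 overlap, so the 8 cannot be set against that rate. In VAT 3 the muscle list took 4.65% of the counts, against 0.297% in the nearest of the other 3 VAT libraries. VAT 3 also held 7420 CPM of miR-1-3p (nearest 782) and 1640 CPM of the muscle miRNA miR-206 (nearest 231). In IMAT 2 miR-206 reached 217000 CPM (nearest 98100), where the lowest TMM factor (0.301) raises the scaled values. In VAT 5 miR-21b, of wide expression, reached 222000 CPM (nearest 51900). In IMAT 5 let-7e reached 42600 CPM (nearest 9360). miR-10b, of a Hox cluster, reached 19700 CPM in VAT 4 (nearest 3100) and 60600 CPM in IMAT 5 (nearest 19200).

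The muscle miRNAs were higher in IMAT than in SAT and VAT, and VAT 3 held more of them than the other VAT libraries. Muscle material of 1 fixed makeup, as the only source above the VAT mean, is argued against by the log2 ratio of miR-1 to miR-499a. Above that mean, the ratio was 11 ± 0.509 in IMAT and 8.58 ± 0.544 in SAT (SD, n = 5 each, difference 2.41, two-sided exact permutation p = 0.0079). The VAT mean of miR-1 rests on VAT 3. The ratio takes other sources to be equal in all depots, so it cannot decide on a fixed makeup beside another source of miR-499a. Muscle material in the collagenase-released adipocytes, of varying makeup or of a fixed makeup beside another source, remains a candidate explanation. Within depots, the log2 deviation of miR-1 rose with those of miR-133a (r = 0.880), miR-206 (0.964) and miR-499a (0.788). The mean was 0.877 over 14 libraries (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 2e-05 over the 2 correlations computed). The Spearman value was 0.845 (permutation p = 0.00015). Without VAT 3 and VAT 4 the mean was 0.812, and the median for the other named miRNAs was -0.01. Joint expression of these miRNAs by the adipocytes would give such correlations too, so the correlations cannot tell it apart from muscle material. With no muscle sample in the series, expression by the adipocytes themselves, as a difference between depots, was not tested and stays open.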

How the results depend on the processing

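Limma on log2 values was the test planned before the data were seen, and became an alternative when edgeR replaced it. Alternatives chosen only after the result was seen were DESeq2, library totals, joined entries, named entries only, and leaving out entries with a zero beyond counting error.

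Counts of differing entries are given in the order IMAT against VAT, SAT against VAT, IMAT against SAT and any depot, with 44, 41, 22 and 58 as reported. Where a count moved by no more than a factor of 1.5 it is left out. Without a filter the counts were 26, 17, 11 and 35, where more entries were tested. With DESeq2 they were 88, 63, 47 and 88. In the planned limma test, the counts other than SAT against VAT were 176, 174 and 202, with a pseudocount of 0.1 they were 170, 160 and 181, and with quantile normalization 77, 48 and 89. All 4 moved with a pseudocount of 10 (178, 71, 175 and 210) and with array quality weights (187, 74, 211 and 236). With library totals the same 3 were 162, 131 and 148. In fits of only the depots compared, IMAT against VAT gave 27 and IMAT against SAT 38. Without entries that had a zero beyond counting error, IMAT against SAT gave 35. The cause of these moves was not tested separately. For IMAT against VAT, the planned limma test gave 16 higher and 160 lower, and library totals 18 and 144. Neither uses TMM or another scaling beyond the totals. Quantile normalization in limma gave 50 and 27, so the large rise in lower entries went with the missing scaling.

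Without 1 library the counts ranged from 33 to 68, from 26 to 48, from 15 to 47 and from 42 to 80, and the share of variance between depots from 49.3 to 55.2%. Under all other alternatives this share lay between 40.2 and 61.0%.

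Of the named miRNAs, 63 differences were called, none of which reversed, and 25 kept their call in every alternative. Without a filter 28 of the 63 lost their call, with the muscle miRNAs left out of the totals 21, with the replicate block 18, in fits of only the depots compared 14, and with library totals and with a pseudocount of 0.1 11 each. Without 1 library 3 to 17 did (17 without VAT 1, 15 without IMAT 2 and without IMAT 4), under each other alternative 10 or fewer, and with DESeq2 and the robust fit none. Over all alternatives the called differences kept their direction, with the call kept in 1660 fits and lost in 291. Uncalled ones stayed uncalled in 3327 fits and gained a call in their direction in 487. All 11 list calls were lost with an estimated correlation, as were 90 of the fits of called lists in all, with 223 kept. Uncalled lists stayed so in 959 fits and gained a call in 14.

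Differences that were not called changed sign with a call in 24 fits. Between IMAT and VAT, miR-143-3p was -1.48 in limma, -1.48 and -1.47 with pseudocounts of 0.1 and 10, -1.21 with quantile normalization and -1.61 with weights. In limma and with both pseudocounts miR-199a-5p was -1.33 and miR-199a-3p -1.35; with weights they were -1.53 and -1.59, and with library totals -1.29 and -1.41. Between IMAT and SAT, weights gave miR-143-3p -1.23, miR-375-2-3p -1.67, miR-210-5p -0.62, miR-193-3p -1.53 and miR-10d-5p -1.59. There miR-10a-5p was -1.67 in limma, -1.67 and -1.66 with the pseudocounts and -2.11 with weights. These limma fits use the deposited CPM, which holds no TMM factor. The epithelial list's median, SAT against VAT, was -0.0389 with median-ratio scaling, and the cause was not tested.

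The replicate block assumed that replicate numbers pair the samples, which the data did not bear out. Over 13 pairs with the same number, the correlation of deviations from the depot mean was -0.24 to 0.19, with 3 above 0.1 and a mean of 0.011, against -0.0024 for different numbers. With the block 28, 27, 16 and 35 entries differed.

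The simulated counts had the TMM-scaled depths and left out the depots' difference in muscle share. In them 29.3, 26.0 and 25.3% of 4-fold changes and 57.3, 62.0 and 62.7% of 16-fold changes were found, in the order of comparisons above. Of the 16-fold changes 84.7% were found at or above the median level and 38.5% below it, and of the 4-fold changes 43.9 and 6.8%, so an uncalled miRNA is not shown to be alike between depots.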

Other observations

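The tests of scaling and of muscle material for miR-196a, miR-196b and miR-204, and the test of scaling for miR-146a, were chosen only after the result was seen; the correlation of miR-146a with white blood cell miRNAs and the comparisons with other splits were fixed before.

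Some miRNAs were listed at 0 in every library of a depot, and are named here after their values were seen. miR-135a-5p was listed at 0 in all 5 IMAT libraries. Set against a floor of 3 counts over the depot's summed depth, its log2 fold change was -4.84 or lower against VAT. This floor takes zeros as counting zeros. Some zeros here lie beyond counting error, so the values given are bounds only where that holds. It was also listed at 0 in SAT 2, beyond counting error, so IMAT and SAT overlapped and the bound of -4.67 against SAT rests on the other 4 SAT libraries. miR-202-3p was listed at 0 in VAT and averaged only 0.915 CPM in SAT, higher by a log2 of at least 3.67 on this floor. It was also listed at 0 in SAT 3 and SAT 5, so the depots overlapped. miR-190a-5p was listed at 0 in SAT, at a log2 of -2.82 or lower against VAT, and averaged 0.468 CPM in IMAT. Over the 3 depots together miR-202-3p and miR-190a-5p did not pass (edgeR adjusted p = 0.079 and 0.061).

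miR-196a, miR-196b and miR-204 were higher in SAT and in IMAT than in VAT, which shares its 4 libraries between both comparisons. Scaling is argued against: the lowest of the 6 log2 fold changes over 5 scalings was 2.94, with a highest adjusted p of 0.013 (edgeR, and limma for quantile normalization). miR-196b and miR-204 were above 0 in all 4 VAT libraries, while miR-196a was listed at 0 in 2 of them, which leaves the size of its difference open. Were they to come only from muscle material of a fixed makeup, they would be higher in IMAT than in SAT as the muscle miRNAs are. The called muscle miRNA nearest to 0 was higher by 2.48, and the highest upper limit (log2 fold change plus 2 SE) was 1.97. The error of the 2.48 was left out, so this does not decide for miR-196a (0.229 ± 0.865, SE) and miR-196b (1.13 ± 0.42). The upper limit of miR-204 was -0.517, which argues against such a sole source for miR-204. A partial contribution of muscle would raise them less, so such a contribution stays open. A difference in body position between the depots, which may set Hox-cluster miRNAs, stays a hypothesis that was not tested further.

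miR-146a was higher in VAT than in SAT and IMAT. Against IMAT, scaling is argued against: the log2 fold change nearest to 0 over 5 scalings was -2.03, with a highest adjusted p of 0.0038 (edgeR, and limma for quantile normalization). Against SAT, scaling stays open, since quantile normalization brought the difference to -0.90 and ended the call (limma adjusted p = 0.24, the highest over all alternatives), while the other 4 scalings kept it. White blood cells among the adipocytes cannot be told apart from expression by the adipocytes: within depots miR-146a had a correlation of 0.306 with the mean of miR-150, miR-155 and miR-142b over 14 libraries (permutation p = 0.59, adjusted p = 0.59; Spearman 0.0901, permutation p = 0.78; 0.0318 without VAT 4 and VAT 1), and the spread of 14 libraries leaves either sign open. These 3 white blood cell miRNAs had negative estimates that did not pass, in SAT against VAT (-0.39, -2.31 and -2.77, edgeR adjusted p = 0.76, 0.12 and 0.17) and in IMAT against VAT (-1.06, -1.75 and -2.91, edgeR adjusted p = 0.15, 0.17 and 0.12). Among them miR-142b was listed at 0 beyond counting error in VAT 4, which held the lowest VAT share of miR-146a (9.83%). This zero enters the correlation. A difference between depots in the adipocytes stays open as well, and was not tested.

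Each real count of differing entries was the highest of the splits drawn. In 100 splits of the libraries, including the real one, only 1, the real split, gave as many. This is the smallest share these splits can give. The other splits mix libraries of depots that differ in whole profiles, so their counts are not those of alike groups. Samples may not be separate fish, so chance between fish cannot be judged from this. Between IMAT and VAT the real count was 44 and the highest other 18, between SAT and VAT 41 and 4, between IMAT and SAT 22 and 2, and over any depot 58 and 4.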
